A study of Homo sapiens with 16 samples.

How the data were processed

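Per the labels' protocols, mRNA was taken from mouse brains with oligo(dT) beads, immunoprecipitated with 2.5 µg of anti-BrdU antibody per brain and made into cDNA libraries. The labels give 4 input and 4 IP libraries for each of the HCC1954 and MDA231 lines. Per the submitters' processing notes, STAR and HTSeq were used with the GRCh38 and GRCm38 builds; their versions are not given in the sources used here.

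The files analysed are 2 tables of Gene Ontology biological process terms, 1 per line. Per the file headers, each row gives a term, the number and percent of listed genes in it, the gene identifiers, the list and background totals, an enrichment p-value, a fold enrichment, Bonferroni and Benjamini adjusted p-values and a false discovery rate. The deposited fold enrichment is the ratio of the listed share of genes to the background share. The enrichment tool, its version, the test and the choice of listed genes are not given in the sources used here. The last deposited column has no name and holds 12 values per table. These equal −log10 of the unadjusted p-value in the authors' HCC1954 table and −log10 of the Benjamini p-value in the authors' MDA231 table, within 0.001, and were not used.

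Each deposited p-value was compared with an upper-tail hypergeometric probability computed after 1 gene was taken from the term's count and from the list. The ratio of the recomputed to the deposited p-value was 1 for each HCC1954 term and between 0.976 and 1.02 for MDA231 terms. The deposited adjusted p-values follow 1 − (1 − p)^(N/rank) with tied p-values sharing a rank, which gave 707 tested terms for HCC1954 and 6488 for MDA231. The ranks recovered this way ran without a gap over 30 and 195 distinct p-values, so no rank is missing below the listing limit; a missing tied term would not be seen. In 3 MDA231 terms the deposited count is 1 lower than the number of identifiers, and the deposited count was used. The number of submitted genes was derived from count and percent.

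Ensembl gene identifiers were matched to symbols. All 30 HCC1954 genes and 2645 of 2646 MDA231 genes had a symbol. Coordinates are from GENCODE release 29 on GRCh38. Intervals of a fold are exact (Clopper-Pearson) 95% binomial intervals of the term's listed genes among the list, divided by the background share. They cover the draw of genes only, and no interval covers the spread between libraries. The size of the term does not enter them, so an upper bound can pass the largest fold possible. The depth per library is not known here.

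The themes (15 sets of name patterns), the gene lists (18), the tests and the rule for named items were fixed before the data were examined. Named terms were the 10 with the smallest adjusted p per table and the leading term of each theme. Named genes were the 20 found in most terms per table (ties by name) and listed members of the gene lists, at most 5 per list by number of terms; not every gene the rule takes is named in the text. The interferon and epithelial members beyond 5 and the HCC1954 terms and genes outside the rule were added after their values were seen. So were CDKN2B, MTAP and the MDA231 terms mitotic nuclear division and protein phosphorylation. Theme shares were compared with a two-sided Fisher's exact test and Benjamini-Hochberg adjustment over the 15 themes. Shared genes were set against a hypergeometric expectation in 16792 background genes, a test chosen after the data were examined. Tests of the gene lists (upper-tail hypergeometric at the listed share of the background, adjusted over 18 lists) were added after the data were examined. They take every list member as part of the background and count only genes printed in a listed term, so fewer genes are counted than were listed.

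The recomputed p-value was tried on independently drawn simulated terms with known folds, 200 raised among 2000. The step-up Benjamini-Hochberg adjustment was used there in place of the deposited one. At the HCC1954 list size of 66 genes, 18.5% of terms raised 10-fold and 74% of those raised 50-fold were called. For MDA231, with 3626 genes, 40.5% of terms raised 2-fold and 88% of those raised 4-fold were called. Unraised terms called numbered 0 and 0 for HCC1954, and 2 and 1 for MDA231.

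Alternatives set before the data were examined were a threshold of 0.01, collapse of terms whose genes overlap at a Jaccard index of 0.5 or more, terms of at least 10 background genes, adjustment over the listed terms alone, term names without case and punctuation, a single theme per term and, for shared genes, genes in at least 2 terms. Added after the data were examined were, for the gene lists, genes in at least 2 terms, unadjusted p-values, a one-sided Fisher's exact test on the full count, and leaving out the gene found in most terms. The planned tests of IP against input need values per library and were left out. Python 3.11.15, SciPy 1.17.1 and NumPy 2.4.6 were used.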

Results

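Brain metastases of 2 breast cancer lines were profiled by Flura-seq, a method that labels new RNA in cells able to convert 5-fluorocytosine and then recovers the labelled RNA with an antibody. HCC1954 is an ERBB2-positive line and MDA231 a triple-negative one, and a brain-metastatic derivative of each was grown in mouse brain for 30 days. Mice received 250 mg/kg 5-fluorocytosine 12 hours before the brains were taken. The series holds 16 libraries in 4 groups of 4, input and immunoprecipitated (IP) RNA for each line. The values analysed here are 1 table of enriched Gene Ontology biological processes per line, and no value per library enters any comparison. Library depth and the spread between replicates are therefore unknown here, and no value below has a replicate error. No source used here states how the genes of either list were chosen, or whether they were higher or lower in the IP RNA, so each list is called the HCC1954 list or the MDA231 list with no direction.

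The HCC1954 list was small. From the counts and percentages in the authors' deposited table it held 88 submitted genes, of which 66 had a biological process, and 37 terms were listed. The MDA231 list was much larger, with 4197 submitted genes, 3626 with a biological process and 314 terms in the authors' deposited table. Both used a background of 16792 genes, so the lists covered 0.393% and 21.6% of it. The sources used here do not say whether that background was limited to genes detected in these cells. A fold may therefore also reflect which genes are expressed at all, and this was not tested. The deposited adjusted p-values correspond to 707 tested terms for HCC1954 and 6488 for MDA231.

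In the HCC1954 table, the leading pair of terms by p named 5 genes: TGFB1, the cytokine transforming growth factor beta 1; AXL, a receptor tyrosine kinase; GAS6, the ligand of AXL; BMP7, a bone morphogenetic protein; and HMGA2, a chromatin protein. Protein kinase B signaling held AXL, GAS6 and TGFB1 and was enriched 23.1-fold in the authors' deposited table (95% exact binomial interval computed here 4.82 to 64.7; unadjusted p = 0.00721, adjusted p = 0.994). Epithelial to mesenchymal transition held BMP7, HMGA2 and TGFB1, at 22.4-fold in the authors' deposited table (interval 4.68 to 62.8; unadjusted p = 0.00764, adjusted p = 0.934). No HCC1954 term passed an adjusted p of 0.05, and 25 of 37 had an unadjusted p under 0.05 in the authors' deposited table.

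Further HCC1954 terms, none past the adjusted threshold, named some of these genes again. Positive regulation of protein secretion named ANKRD1, APBB1 and TGFB1 at 21.2-fold, and chondrocyte differentiation named CCN3, HMGA2 and TGFB1 at 19.6-fold, in the authors' deposited table. Negative regulation of cell growth held 4 genes, namely APBB1, CCN3, ENPP1 and TGFB1, at 8.41-fold in the authors' deposited table (unadjusted p = 0.0115). Regulation of cell growth added the insulin-like growth factor binding proteins IGFBP4 and IGFBP7 to CCN3, at 9.54-fold in the authors' deposited table. Organ morphogenesis named APLP1, ONECUT2 and EREG, a ligand of the epidermal growth factor receptor family, at 8.30-fold in the authors' deposited table. Extracellular matrix assembly rested on GAS6 and TGFB1, which are 2 of its 7 background genes, with a fold of 72.7 in the authors' deposited table (interval 8.85 to 252). The broadest term, signal transduction, held 10 genes, among them AXL, GAS6, HMGA2, FGF14, IGFBP4 and APBB1, at 2.19-fold in the authors' deposited table. Positive regulation of protein kinase B signaling again held AXL, GAS6 and TGFB1, at 9.09-fold in the authors' deposited table. Pairs of genes made up positive regulation of superoxide anion generation (CYBA and TGFB1), type B pancreatic cell proliferation (CCN3 and IGFBP4), secretion by cell (AXL and STX1A), positive regulation of cell cycle arrest (HMGA2 and TGFB1), phosphate-containing compound metabolic process (ENPP1 and TGFB1) and positive regulation of transcription regulatory region DNA binding (HMGA2 and TGFB1), at 20.4-fold to 56.5-fold in the authors' deposited table. Transport named a separate set of 5 genes, GJA3, LAPTM5, PITPNM2, SLC25A30 and SYPL2, at 3.66-fold in the authors' deposited table.

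AXL and GAS6 stood together in 9 of the 37 HCC1954 terms and were the sole members of 6. Those 6 were immune or clearance processes: negative regulation of dendritic cell apoptotic process, dendritic cell differentiation, positive regulation of natural killer cell differentiation, positive regulation of cytokine-mediated signaling pathway, cellular response to interferon-alpha and apoptotic cell clearance. Negative regulation of dendritic cell apoptotic process had the smallest adjusted p of the HCC1954 terms, 0.746, and the largest fold, 170 in the authors' deposited table, with 2 of 3 background genes listed (interval 20.7 to 589). The upper bound lies above 254, the largest fold possible for this list, because the interval does not take in the size of the term.

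**Figure D1:**
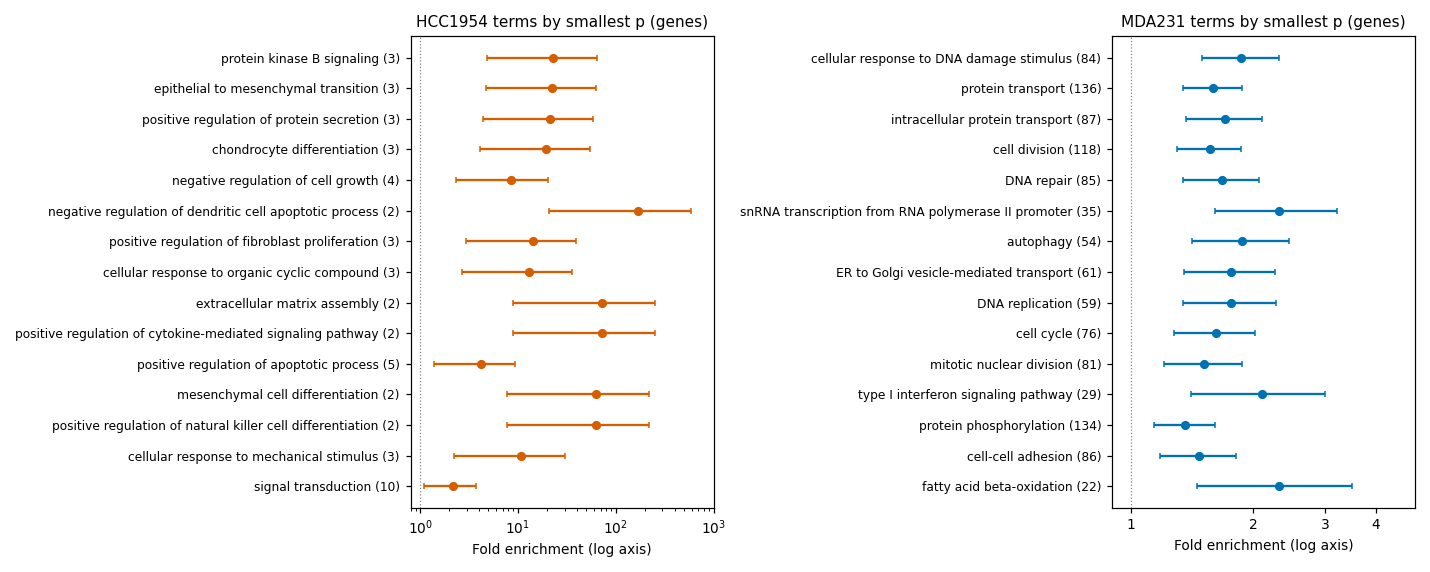
Fold enrichment of the 15 terms with the smallest p in each table, on log axes of different ranges, with the number of listed genes in parentheses. Points are folds from the authors' deposited table and bars are 95% exact binomial intervals of the listed count; the HCC1954 folds run from 2.19 to 170 with wide bars, and the MDA231 folds from 1.36 to 2.32 with narrow ones.

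The 37 HCC1954 terms named 30 distinct genes, of which 16 were in at least 2 terms. TGFB1 (ENSG00000105329; GRCh38 chromosome 19, 41301587 to 41353911, minus strand) was in 21 terms. GAS6 (ENSG00000183087; chromosome 13, 113820549 to 113864067, minus strand) was in 13, and AXL (ENSG00000167601; chromosome 19, 41219203 to 41261766, plus strand) was in 10. HMGA2 was in 8 terms, BMP7 in 7 and CCN3, a matricellular protein, in 6. ANKRD1, APBB1 and EREG were each in 4, and CYBA, ENPP1 and IGFBP4 each in 3. FGF14, GJA3, IGFBP7 and SRGN were in 2, while 14 genes were in 1, among them APLP1, EMP3, HIVEP3 and ITPKA. At least 1 of TGFB1, GAS6 and AXL was in 29 of 37 terms (78.4%). With TGFB1 left out of the list and the background, 17 terms kept a p under 0.1 and 13 a p under 0.05. With TGFB1, GAS6 and AXL left out together, 10 and 6 terms did, and the smallest p was 0.0292, for mesenchymal cell differentiation (BMP7 and HMGA2). The small lists behind these terms limit them, since 19 held 2 genes and 11 held 3.

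**Figure D2:**
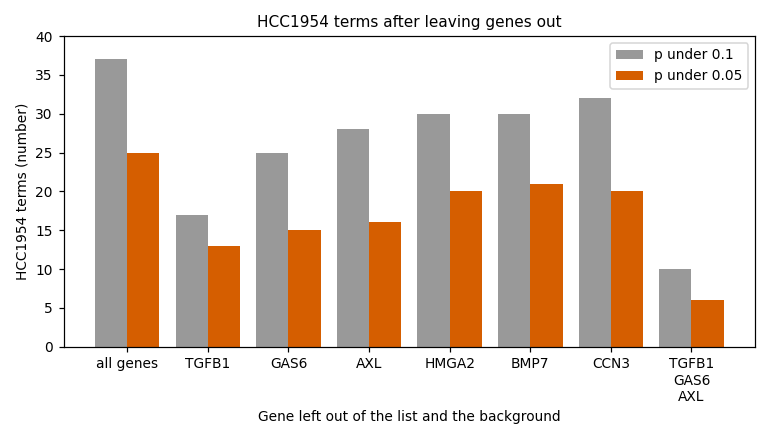
Number of the 37 HCC1954 terms that kept an enrichment p under 0.1 (grey) or 0.05 (orange) after the gene on the horizontal axis was left out of both list and background; the last pair of bars leaves out 3 genes together. The counts go from 37 and 25 with all genes to 17 and 13 without TGFB1.

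In the MDA231 list, genes for genome maintenance, protein traffic and cell division were over-represented against this common background. Cellular response to DNA damage stimulus held 84 of its 208 background genes, including BLM, a RecQ helicase, MRE11, a nuclease of double-strand break repair, SIRT1, a deacetylase, and MYC; it was enriched 1.87-fold in the authors' deposited table (95% exact binomial interval computed here 1.50 to 2.31; adjusted p = 9.41e-06). Protein transport held 136 of 395 genes at 1.59-fold in the authors' deposited table (interval 1.34 to 1.88; adjusted p = 1.22e-05). Cell division held 118 of 350 genes, CDK5 among them, at 1.56-fold in the authors' deposited table (interval 1.30 to 1.86; adjusted p = 0.000256). In all, 15 of the 314 MDA231 terms had an adjusted p under 0.05, with folds of 1.36 to 2.32, and 214 an unadjusted p under 0.05, in the authors' deposited table.

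Genome maintenance and the cell cycle supplied 4 further terms of those 15. DNA repair held 85 of 235 genes at 1.68-fold (adjusted p = 0.00051 in the authors' deposited table) and named BLM, MNAT1, MRE11, MTOR, RPS3 and SIRT1. DNA replication held 59 of 155 at 1.76-fold (adjusted p = 0.00339 in the authors' deposited table), with BLM, KAT5, MCM3, MRE11 and SIRT1. Cell cycle was enriched 1.62-fold (adjusted p = 0.00431) and named CDK5, KRT18, MNAT1 and TAF1 in the authors' deposited table. Mitotic nuclear division, with the mitotic kinase PLK1, was enriched 1.51-fold (adjusted p = 0.0327 in the authors' deposited table). It shared 69 genes with cell division, a Jaccard index of 0.531 and the highest of any pair among the 15. Apart from these, the snRNA transcription term of RNA polymerase II held 35 of 70 genes, a 2.32-fold enrichment with adjusted p = 0.000558 in the authors' deposited table.

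Protein traffic and turnover supplied 3 more. Intracellular protein transport was enriched 1.71-fold (87 of 236 genes; adjusted p = 0.000235 in the authors' deposited table). Autophagy, with the growth kinase MTOR, was enriched 1.88-fold (54 of 133; adjusted p = 0.00124 in the authors' deposited table), and ER to Golgi vesicle-mediated transport 1.77-fold (61 of 160; adjusted p = 0.00243 in the authors' deposited table). Terms near the threshold covered other biology. Type I interferon signaling pathway held 29 of 64 genes at 2.10-fold (interval 1.41 to 3.01; adjusted p = 0.0310 in the authors' deposited table), among them IRF7, ISG15, IFIT2, IFIT3, OAS1, OAS2, OAS3, BST2 and IFI6. Protein phosphorylation, which named ERBB2, GSK3B, MTOR, PLK1, TAF1, TGFB2 and TGFBR2, was enriched 1.36-fold (adjusted p = 0.0350 in the authors' deposited table). Cell-cell adhesion was enriched 1.47-fold (adjusted p = 0.0462) and fatty acid beta-oxidation 2.32-fold (22 of 44 genes; adjusted p = 0.0448), both in the authors' deposited table.

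Just outside the threshold lay mitochondrial translation, with 19 of 36 genes and a 2.44-fold enrichment (adjusted p = 0.0544 in the authors' deposited table), and response to endoplasmic reticulum stress, at 1.91-fold (adjusted p = 0.0761 in the authors' deposited table). The leading terms of other themes did not pass. Face development was enriched 2.83-fold (adjusted p = 0.298), neuron projection development 1.57-fold (adjusted p = 0.503), p38MAPK cascade 3.97-fold (adjusted p = 0.524), blood vessel development 1.95-fold (adjusted p = 0.569) and microtubule nucleation 2.32-fold (adjusted p = 0.774), all in the authors' deposited table. A fold in this table has a ceiling of 4.63, reached where every background gene was listed, as in 10 terms.

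No gene dominated the MDA231 terms, which named 2646 distinct genes. SIRT1 was in the most, 23 of 314 (7.32%), followed by TAF1, a subunit of transcription factor TFIID, in 18. CASP8, FADD, MTOR and TNFAIP3 were each in 16 terms, BLM, CDK5, MYC and TRAF2 in 15, TRAF6 in 14, and CDKN2A, CTNNB1, GSK3B, KAT5, MRE11 and PLK1 in 13. DNAJA3 and MNAT1 were among those in 12. The 15 terms with an adjusted p under 0.05 named 838 of the 2646 genes and 13 of the 20 genes found in most terms. SIRT1 left out, 15 terms still had an adjusted p under 0.05.

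Gene groups fixed before the data were examined were then looked up among the named genes. In the MDA231 table, 11 of 14 interferon response genes were named, where the listed share of the background would give at most 3.02 (exact upper-tail hypergeometric p = 8.86e-06, adjusted over 18 lists 0.000159). Of these 11, 10 are members of the type I interferon signaling pathway term given above, so this is not a separate result. Epithelial markers followed with 8 of 14 (exact hypergeometric p = 0.00398, adjusted p = 0.0358). They were the transcription factor GRHL2, the junction genes CDH1, CLDN3 and OCLN, the keratins KRT7, KRT8 and KRT18, and the mucin MUC1. With only genes in at least 2 terms counted, 7 remained and the adjusted p was 0.159 by the same test. That alternative kept all 3626 listed genes as reference, though 1599 genes were in at least 2 terms. Its larger p-value therefore does not show a weaker result. Hypoxia and glycolysis genes numbered 5 of 13 (ENO1, ADM, SLC2A1, HK2 and PGK1; exact test, adjusted p = 0.772). Inflammatory genes numbered 6 of 18, with TNFAIP3, CCL2, CCL5, ICAM1 and CXCL10 in the most terms (exact test, adjusted p = 0.787), and Wnt, Notch and TGF-beta genes 5 of 18 (CTNNB1, TGFBR2, SMAD4, WNT5A and NOTCH1; exact test, adjusted p = 1).

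The remaining lists had few named members in the MDA231 table. The ERBB and receptor tyrosine kinase list had ERBB2 and ERBB3 of 15 genes, the proliferation list PLK1 and MCM3 of 17, antigen presentation TAP1 and TAP2 of 11, and the integrin and adhesion list ITGAV and CCN1 of 21. A single member was named for extracellular matrix (COL1A1), mesenchymal markers (TGFB2), the cytosolic ribosome (RPS3), neuronal genes (MAP2) and endothelial genes (PECAM1), and none of the oxidative phosphorylation, astrocyte, microglia and oligodendrocyte lists. In the HCC1954 table, the named members were AXL (in both the adhesion and the microglia list), TGFB1 (mesenchymal) and EREG (ERBB), and no list passed an adjusted p of 0.05 (smallest 0.357). A gene that is in a list but in no listed term is not named in these tables, so an unnamed gene may still have been in the list.

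The tables of the 2 lines were next set side by side. They had 0 terms in common (Jaccard index 0) and 0 named genes in common, although 30 genes are named for HCC1954 and 2646 for MDA231. Independent draws from the 16792 background genes would share 4.73 genes, and the probability of 0 was 0.00581 (hypergeometric). Named genes are only those in a listed term and were not drawn evenly, so the overlap of the full lists is not known. For terms, draws from 6488 tested terms would share 1.79, and the probability of 0 was 0.159 (hypergeometric), if both lists could draw on the same 6488 terms. TGFB1, AXL and GAS6 were thus named for HCC1954 and not for MDA231, while TGFB2 and TGFBR2 were named for MDA231 and not for HCC1954. These names do not show in which line a gene was higher. Exchanged tables, or lists of genes lower in the named line, are not excluded.

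Development and morphogenesis terms took a larger share of the HCC1954 table. They were 7 of 37 terms (18.9%, 95% exact binomial interval 7.96 to 35.2) against 13 of 314 for MDA231 (4.14%, interval 2.22 to 6.98), a difference with p = 0.00230 by a two-sided Fisher's exact test and adjusted p = 0.0345 over 15 themes. The HCC1954 members were chondrocyte differentiation, mesenchymal cell differentiation, natural killer and dendritic cell differentiation, organ morphogenesis, oligodendrocyte development and biomineral tissue development. Once overlapping terms were collapsed, the shares were 3 of 16 and 13 of 296 and the adjusted p was 0.618, with shares of 18.8% and 4.39%. Terms share genes and are not independent, so these p-values describe the lists.

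Other themes did not differ past the threshold. Metabolism other than respiration was 1 of 37 terms for HCC1954 (2.70%) and 50 of 314 for MDA231 (15.9%; Fisher's exact p = 0.0264, adjusted p = 0.198), and protein folding, transport and degradation 2 of 37 (5.41%) and 49 of 314 (15.6%; Fisher's exact test, adjusted p = 0.681). RNA processing and transcription was 1 of 37 and 32 of 314 (10.2%; Fisher's exact test, adjusted p = 0.712). Immune and inflammatory signalling was 2 of 37 (5.41%) and 19 of 314 (6.05%; Fisher's exact test, adjusted p = 1) by its name patterns, which miss 4 of the 6 terms of AXL and GAS6 alone and take in fat cell differentiation for MDA231. The nervous system theme, 2 of 37 and 8 of 314, matched dendritic cell terms in the HCC1954 table, which are immune and not neuronal. For MDA231 it took in sphingomyelin biosynthetic process, a lipid term. Epithelial to mesenchymal transition matched no theme pattern and is not in these counts.

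**Figure D3:**
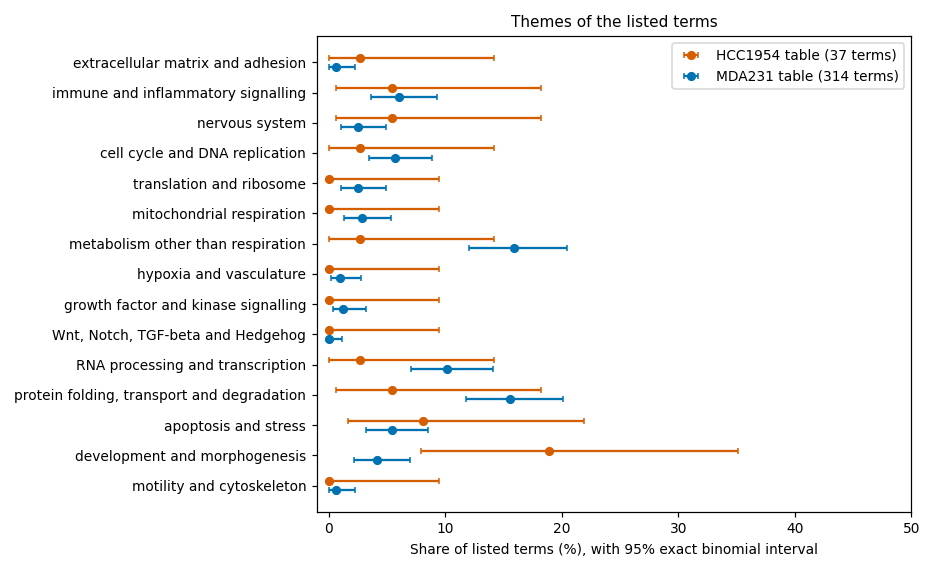
Share of listed terms in each of 15 themes, in percent, for the HCC1954 table (orange, 37 terms) and the MDA231 table (blue, 314 terms), with 95% exact binomial intervals. Development and morphogenesis is the theme whose shares, 18.9% and 4.14%, differed at an adjusted p under 0.05.

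IP RNA was not compared with input RNA in either line, since no value per library was analysed here.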

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

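The share of development and morphogenesis terms differed between the tables of the 2 lines (7 of 37 for HCC1954, 13 of 314 for MDA231; two-sided Fisher's exact test, adjusted p = 0.0345). TGFB1, HMGA2, AXL and GAS6 each stood in 2 of those HCC1954 terms, and after collapse of overlapping terms the shares were 18.8% and 4.39% (3 of 16 and 13 of 296) and the adjusted p was 0.618. Without TGFB1, an alternative chosen after the data were seen, the HCC1954 share was 29.4% (5 of 17) and the adjusted p 0.0164. No biological explanation was tested.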

How the results depend on the processing

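The alternatives with unadjusted p-values, with gene-list members in at least 2 terms, with Fisher's exact test on the full count and without TGFB1 or SIRT1 were chosen after the data were seen. For HCC1954 the count of terms was 0 with adjustment over the listed terms alone and without TGFB1, 25 at an unadjusted p under 0.05 and 7 with Fisher's exact test on the full count, which does not take 1 gene from each small count. A stricter threshold, collapse of terms and a minimum term size can only leave that 0 as it is and say nothing about stability. For MDA231 the count of 15 was 10 at an adjusted p under 0.01, 14 with overlapping terms collapsed, and 15 with terms of at least 10 background genes and without SIRT1. It rose to 114 with adjustment over the listed terms alone, which corrects for 314 tests in place of 6488 and by the step-up procedure, to 214 at an unadjusted p under 0.05 and to 25 with Fisher's exact test on the full count. Shared terms were 0 with names without case and punctuation, and shared genes, 0 to begin with, can only be 0 among genes in at least 2 terms. The number of themes past the threshold, 1, became 0 with overlapping terms collapsed and 0 at an unadjusted p under 0.05, where fewer terms enter (development shares 20% and 3.74%, adjusted p 0.0909), and was 1 with each term in its first theme and without TGFB1. At an adjusted p under 0.01 no HCC1954 term is left, so themes and shared genes gave no value there and 0 shared terms was fixed. No paired analysis was possible because no value per library was analysed here; for the same reason the alternatives foreseen for IP against input (normalization, filter, pseudocount, replicate block, leaving out a replicate) were not run.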

Other observations

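The tests of the 2 explanations on list size and on TGFB1 were written before their results were seen; the tests on shared genes and epithelial markers were chosen after.

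Beyond the leading terms, the MDA231 table holds a wide set of ubiquitin, Golgi and vesicle processes: of 49 terms on protein folding, transport and degradation, 42 had an unadjusted p under 0.05 and 4 an adjusted p under 0.05. Metabolism terms numbered 50, of which 32 had an unadjusted p under 0.05 and 1, fatty acid beta-oxidation, an adjusted p under 0.05. The share of tested terms with an unadjusted p under 0.05 was 3.54% for HCC1954 and 3.30% for MDA231. This p-value takes 1 gene from each count, so the shares are not to be read against 0.05. Among unraised simulated terms, 0.111% to 0.167% were under 0.05 at 66 genes and 1.11% to 2.11% at 3626. Those terms had the sizes of listed terms only, so they give no exact baseline for the 707 and 6488 tested.

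Terms passed the adjusted threshold for MDA231 and not for HCC1954. When 66 genes were drawn at random 10000 times from the MDA231 list, no MDA231 term had an adjusted p under 0.05 in 99.6% of draws, and a median of 1 term per draw had an unadjusted p under 0.05 (95% of draws 0 to 5). A list of that size may therefore miss the MDA231 terms at the folds they had. In simulations at 66 genes, 18.5% of terms raised 10-fold and 74% of those raised 50-fold were called. There 200 of 2000 independent terms were raised and the step-up adjustment was used. The deposited adjustment ran over 707 terms that share genes, so the simulations do not show which terms could be called here. To be listed at an unadjusted p under 0.1 in a list of that size, the 15 MDA231 terms would have needed folds of 3.22 to 17.3, above the folds they had. In the reverse direction, the 36 HCC1954 terms that could be listed for MDA231 at all would have needed folds of 1.08 to 3.31 there (median 1.77). These lie under the ceiling of 4.63, so the terms could have been listed. Some would have needed most of their genes, as extracellular matrix assembly, with 5 of 7 needed and 1.51 expected. A fold under the ceiling does not measure power, so list size is not excluded as a reason for their absence.

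Most HCC1954 terms rest on the same few genes, with at least 1 of TGFB1, GAS6 and AXL in 29 of 37. Without TGFB1, 45.9% of them kept a p under 0.1, but this test decides nothing: TGFB1 was picked for being in the most terms, and 20 of its 21 terms were lost without it, 17 of the 21 holding only 2 or 3 genes. No biological explanation was tested for this, since no expression value of TGFB1 was analysed here.

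The tables name different genes. Epithelial markers and ERBB2, ERBB3 and GRHL2 are in the MDA231 table, though MDA231 is known as a mesenchymal, ERBB2-negative line. The ERBB list as a whole had 2 of 15 genes named, under the 3.24 expected at most from the listed share of the background (p = 0.867 by an exact hypergeometric test). CDKN2A, a gene known to be deleted in MDA-MB-231, is named in 13 of its terms, and CDKN2B and MTAP, near it on chromosome 9, in 2 each. These genes were chosen after their values were seen. A gene deleted in a line gives no RNA there, so CDKN2A argues against a list of genes higher in MDA231 cells, for that gene alone. AXL, TGFB1 and HMGA2, picked from the genes in most terms, are in the HCC1954 table, where the mesenchymal list had 1 of 10 genes named and did not pass (exact test, adjusted p = 0.357). A random draw of the named genes from the background would seldom leave 0 shared (exact hypergeometric p = 0.00581). Lists that exclude each other by construction always would, and the overlap of the full lists is not known. At the listed share of the background, 8 of 14 epithelial markers would seldom be named (exact hypergeometric p = 0.00398, adjusted over 18 lists 0.0358). That background may include genes not expressed in these cells, so the test does not set list size aside. For epithelial genes in at least 2 terms, 7, the adjusted p was 0.159 by the same test, with a reference not reduced to such genes. That larger p-value does not show a weaker result. Exchanged tables and lists that hold the genes lower in the named line cannot be told apart. Lists as named are not excluded by a gene picked afterwards. Epithelial markers were named more often than mesenchymal ones (8 of 14 against 1 of 10, two-sided Fisher's exact p = 0.0333), but the side of the contrast is not given in the sources used here. RNA of the other line or of mouse brain was not tested.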
